A study of Mus musculus with 3 samples.

How the data were processed

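Lungs of wild-type mice were made into single-cell suspensions and profiled by droplet single-cell RNA sequencing, with 1 library each from uninfected mice, mice on day 7 of infection and mice on day 14. The deposited values are raw UMI counts per gene and cell barcode, written by Cell Ranger 6.1.2 per the file headers. Per the submitters' processing notes, FastQC and Cell Ranger were used with the mouse genome build GRCm38.p6. The release of the gene annotation and the number of animals per library are not stated. Each library lists 31053 genes. The values are whole numbers, the 3 libraries had been counted separately, and the lowest total of any barcode was 500 UMIs. Gene positions are from the GENCODE annotation of GRCm38.

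The files held 14300 uninfected, 16369 day 7 and 13831 day 14 barcodes. Barcodes with at least 200 genes and under 15% mitochondrial UMIs passed, and 215, 158 and 42 failed. Doublet scores were computed per library with the scrublet method in scanpy, and the highest-scoring barcodes were removed at a rate of 0.8% per 1000 barcodes, that is 1587, 2102 and 1521 barcodes (11.27%, 12.97% and 11.03%). The 12498, 14109 and 12268 kept cells had median depths of 3893, 4808 and 2480 UMIs.

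Kept cells of the 3 libraries were clustered together without batch integration. Counts per cell were scaled to 10000 and log-transformed. From the variable genes, the fixed gene lists were left out, except those of alveolar macrophage identity, surfactant and extracellular matrix. Cell cycle, mitochondrial, ribosomal, hemoglobin, sex-linked and receptor variable segment genes were left out too. The 3000 most variable of the remaining genes gave 40 principal components, a graph of 15 neighbours and Leiden clusters at a resolution of 1.5, with a seed of 1. A cluster was named when at least 3 markers of a fixed set were among its 10 leading genes by fold (detected in at least 20% of its cells) and at least 3 were past 2-fold. Otherwise it took the set with the highest mean log2 fold, if that was at least 0.5 with at least 3 markers past 2-fold and no other set had more markers among the leading genes. Clusters whose median UMI count lay under 1 in 3 of their library's were not named by this second way. Unnamed clusters with Csf1r, Cd68, Adgre1, Fcgr1 and Lyz2 all at least 2-fold above lymphocyte-like cells, and a median UMI count of at least 1 in 3 of their library's, are called unnamed phagocytes. This rule was chosen after the clusters were seen.

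With 1 library per group there is no spread between replicates, so no test of a difference between conditions was made, and neither a p-value nor a standard error is given. Shares of kept cells have exact Clopper-Pearson 95% intervals. Ratios of shares and of summed counts have exact conditional binomial 95% intervals. Within a class, UMIs were summed over its cells and divided by the class total, with exact Poisson 95% intervals for levels. Classes with at least 50 cells in both libraries were compared, for genes with at least 20 summed UMIs. Single Trdc-positive cells were compared without that minimum of cells. A gene with no UMI in 1 library is given as at least N-fold different, against a floor of 3 counts summed over the class. Shares of cells with a UMI are also given after each cell was thinned to 1000 UMIs, leaving out shallower cells, with B-like cells as a measure of free RNA. Free RNA may be higher in other classes.

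The lists, fixed before the data were examined, cover IL-1 and IL-23 pathway cytokines, the type 17 and type 1 lymphocyte programs, interferon γ and type I interferon response, and MHC class II presentation. They also cover neutrophil chemoattractants, monocyte and lymphocyte chemoattractants, antimicrobial effectors, NF-κB and inflammatory response, alveolar macrophage identity, lipid handling, glycolysis and hypoxia, oxidative phosphorylation and proliferation. The others are T cell activation and checkpoint, surfactant, dissociation stress, hemoglobin, vascular activation, extracellular matrix and regulatory genes. A list's median log2 ratio is given minus that of all genes of the class, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list is described as higher or lower at or past percentiles 97.5 and 2.5. Members are counted at a 2-fold difference by size, leaving out those whose level in the class is under 5% of that in the class with most, which free RNA could give.

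Genes were named by a rule set before the data were examined. For each main class and each ratio of an infected library over the uninfected one, the rule takes 6 higher and 6 lower genes whose interval bound nearest to no difference lies farthest from it. It asks that the level in the class is at least 5% of that in the class with most. Mitochondrial, ribosomal, hemoglobin, sex-linked, receptor variable segment and predicted genes are left out. It adds list members at least 2-fold different with an interval that excludes equality, and the type 17 and cytokine genes of the planned comparisons whatever their values. The text gives a selection of these.

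The intervals were tested on simulated data, with 200 genes changed by a known fold. Class sums were drawn with Poisson counting error, which the intervals assume, and without spread between cells. The rates therefore check the computation and not how well the intervals suit these cells. In mononuclear phagocytes the 95% interval held the true ratio for 95.7% of 13363 unchanged genes on day 7 (13556 genes tested) and 95.6% of 12432 on day 14 (12628 tested). The direction was recovered for 83.1% and 85.9% of genes changed 1.5-fold, 93.8% and 86.6% of those changed 2-fold, and 100% and 98.5% of those changed 4-fold. In γδ T-like cells it held for 96.9% of 9849 unchanged genes on day 7 (10036 tested) and 96.6% of 6179 on day 14 (6353 tested). Directions there were recovered for 31.2% and 36.1% at 1.5-fold, 59.7% and 65.0% at 2-fold and 91.8% and 96.2% at 4-fold.

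Alternatives fixed before the data were examined were a stricter cell filter (at least 500 genes and under 10% mitochondrial UMIs), doublets kept, a doubled resolution of 3, all variable genes (fixed lists other than proliferation kept in clustering), median-of-ratios scaling, equal weight per cell, a minimum of 100 summed UMIs for list members, and single Trdc-positive cells in place of the γδ T-like class. Chosen after seeing the data were Trdc-positive cells with no marker exclusion, shares among leukocytes only, and clusters of shallow cells left out. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.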

Results

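Lung cells of wild-type mice were profiled by droplet single-cell RNA sequencing in 3 libraries. The libraries stand for uninfected mice, mice on day 7 of infection and mice on day 14, with 1 library each. The series title names macrophages, IL-1β, IL-23, γδ T cells and non-tuberculous mycobacteria. Labels do not state how many animals each library holds. There are no replicates, so no difference was tested between conditions, and every interval given here is a 95% interval that covers counting error only. A difference between libraries is a difference between those libraries, since nothing shows how far 2 libraries of 1 group would lie apart.

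The uninfected library held 14300 barcodes and 73102538 unique molecular identifiers (UMIs, each standing for 1 captured transcript). The day 7 library held 16369 barcodes and 102208360 UMIs, and the day 14 library 13831 barcodes and 58189094 UMIs. Median UMIs per barcode were 3917.5, 4978 and 2614, and no barcode in any library had fewer than 500. After filtering and removal of likely doublets, 12498 uninfected, 14109 day 7 and 12268 day 14 cells were kept. The name of the day 14 library carries another run code than the other two, so whatever that code marks cannot be told apart from day 14. Cells were clustered together and clusters were named from fixed markers, and each class is called "-like" because it rests on transcripts alone. Unless said otherwise, levels are UMIs of the gene per 1000000 UMIs of the class (CPM), and ratios are on a log2 scale with the interval in parentheses.

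The first comparison asks which cells made up the lung suspension before infection and on each day. γδ T-like cells, innate-like lymphocytes that can release IL-17 quickly, made up 1.01% (0.8405 to 1.20%) of cells in the uninfected library, 14.75% (14.2 to 15.35%) on day 7 and 2.57% (2.295 to 2.86%) on day 14. The day 7 share was 14.6 (12.2 to 17.65) times the uninfected one and the day 14 share 2.55 (2.065 to 3.16) times. Among T, NK and innate lymphoid type 2-like cells together, γδ T-like cells made up 3.83%, 56.4% and 7.34%. Per B-like cell there were 0.0859, 2.03 and 0.0866 of them, and per αβ T-like cell 0.0751, 1.566 and 0.0922. The day 14 excess was thus hardly seen against B-like cells and small against αβ T-like cells, whose own shares were higher that day. Mononuclear phagocytes (macrophage-like, monocyte-like and unnamed phagocytes together) were 32.2% (31.4 to 33.0%) of uninfected cells, 49.3% (48.5 to 50.1%) on day 7 and 19.5% (18.8 to 20.2%) on day 14, and the day 7 excess was smaller among leukocytes alone.

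The make-up of the phagocytes differed as well. Alveolar macrophage-like cells, the resident scavengers of the air spaces, were 18.0% of uninfected cells, 10.8% on day 7 and 1.81% on day 14. Of their clusters, cluster 42, with a mean marker log2 fold of 0.9867, was at 0%, 2.367% and 0.163%. Interstitial macrophage-like cells had higher shares in both infected libraries, at 4.34%, 13.9% and 7.94%, but their clusters differed. Cluster 19, with the highest mean marker log2 fold of them (3.64), was lower in both, at 3.297%, 0.9994% and 0.1793%. Cluster 28 (1.236) was at 0.6641%, 4.813% and 3.008%. Clusters 30 and 38, with mean folds of 0.3264 and 0.4275, were at 0.3681%, 4.047% and 0.8803%, and 0.008001%, 3.997% and 3.872%. Cluster 38 held 475 of the 974 day 14 cells of the class and 1 of the 542 uninfected ones. The day 14 excess thus depends on cluster 38. Monocyte-like cells were 9.78%, 1.37% and 5.22%. A pair of clusters, 37 and 39, carried phagocyte genes but matched no marker set and are kept as unnamed phagocytes, by a rule set after the clusters were seen. Together they were 0.0560% of uninfected cells, 23.2% on day 7 and 4.56% on day 14. Cluster 39 drew 2851 of its 3152 cells from the day 7 library, so it may stand for that library and not for a cell type. Clusters 11 and 25 carried the same phagocyte genes but were too shallow for that rule. Their cells, 2.496% of uninfected, 0.347% of day 7 and 0.0734% of day 14 cells, are not counted as phagocytes. Cluster 30, named by its leading markers, is counted though shallower still. Its median UMI count was 0.2047 of its library's, against 0.2438 and 0.3106 in clusters 11 and 25. With shallow clusters left out, the day 7 log2 ratio of the phagocyte share was 0.50, against 0.61 with all clusters.

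Neutrophil-like cells, the first granulocytes to enter infected tissue, were 1.49%, 1.86% and 8.34% of cells, a day 14 share 5.60 (4.79 to 6.59) times the uninfected one. B-like cells were 11.7%, 7.265% and 29.7%, and αβ T-like cells 13.4%, 9.42% and 27.9%, so both shares were lowest on day 7 and highest on day 14. NK-like cells were 10.8%, 1.33% and 3.89%. Endothelial-like cells stood at 7.465%, 1.74% and 1.77%, and fibroblast-like cells at 6.37%, 0.957% and 0.367%. Conventional dendritic-like cells, which present antigen to T cells, were 5.85%, 7.215% and 2.48%, and the day 7 difference was no longer detectable at the doubled clustering resolution or among leukocytes alone. The minimum of 500 UMIs per barcode and the lower depth of the day 14 library can shift shares of shallow cells such as neutrophils and lymphocytes, and shares of a suspension are not cell numbers per lung.

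**Figure D1:**
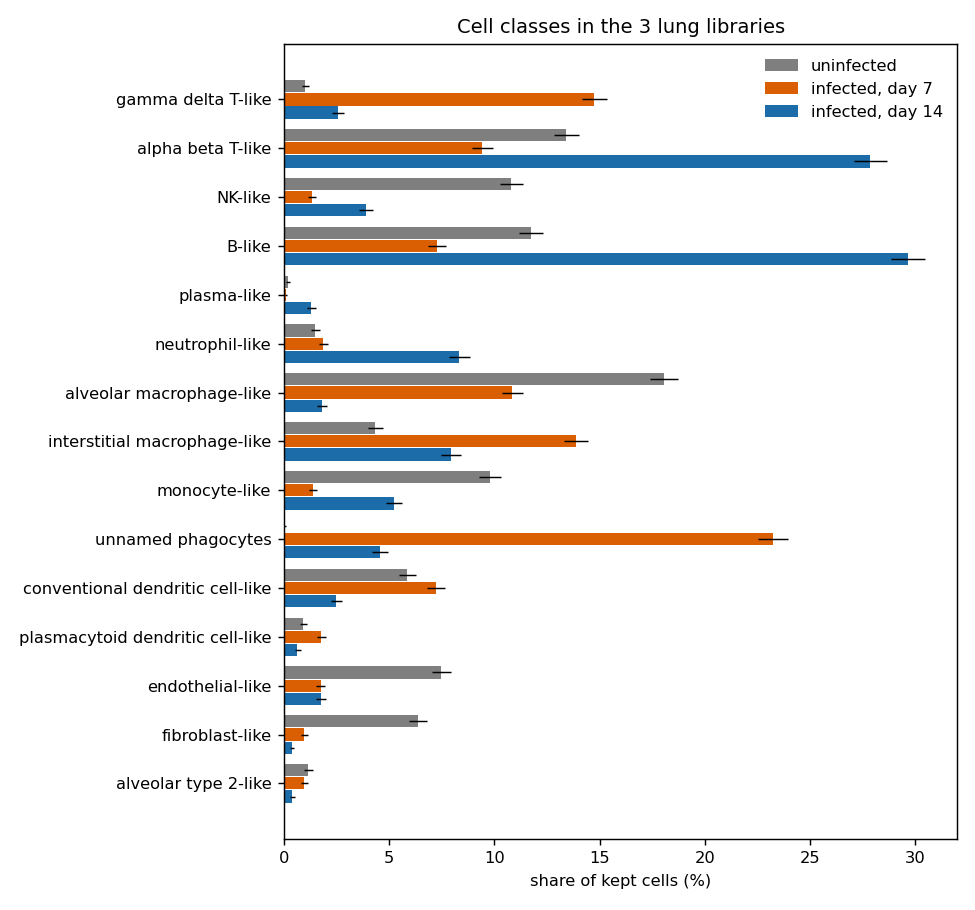
Share of kept cells (%, horizontal axis) of 15 cell classes (vertical axis) in the uninfected, day 7 and day 14 libraries; bars are the shares and lines the exact 95% binomial intervals. γδ T-like cells stand at 1.01%, 14.75% and 2.57%.

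The size of the γδ T difference depends on which cells are counted, because the 126 uninfected cells of the class were mixed. Trdc (ENSMUSG00000104876, chromosome 14, 54142851 to 54148868 of GRCm38), the constant gene of the δ receptor chain, had a UMI without any Trac UMI in 12.7% of those uninfected cells, against 51.6% on day 7 and 46.0% on day 14. Trac, the constant gene of the α chain, had a UMI without Trdc in 26.2%, 5.24% and 9.52%. In B-like cells, which should lack Trdc, 0.0682%, 0.0976% and 0.0550% of cells had a Trdc UMI. After each cell was thinned to 1000 UMIs, Trdc was seen in 6.40%, 28.0% and 29.8% of the class, with 1, 70 and 10 shallower cells left out. At a doubled clustering resolution 99 of the 126 uninfected cells joined innate lymphoid type 2-like clusters and 27 stayed, and the day 7 share was then 67.04 times the uninfected one. Counting single cells with Trdc and Cd3 UMIs and none of Cd8b1, Cd79a or Lyz2 gave 25, 247 and 137 cells. Their shares were 0.200%, 1.75% and 1.12%, with the day 7 share 8.75 times (5.79 to 13.79) the uninfected one. Without the exclusion of those markers, which also leaves out day 7 cells that hold Lyz2 RNA, the shares were 0.336%, 8.97% and 1.69%, from 42 uninfected, 1266 day 7 and 207 day 14 cells. Each of these definitions put the uninfected share lowest and the day 7 share highest.

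The second comparison asks what the γδ T-like cells transcribed, in particular the IL-17 genes that IL-1β and IL-23 are known to induce. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496), a cytokine that draws neutrophils, stood at 509.7 (447 to 579) CPM in the uninfected class, 3060 (3020 to 3100) on day 7 and 2982 (2863 to 3106) on day 14. Its log2 ratio over uninfected was 2.59 (2.40 to 2.78) on day 7 and 2.55 (2.355 to 2.75) on day 14, and both were larger when likely doublets were kept or single Trdc-positive cells were taken. The Trdc-positive comparison rests on 25 uninfected cells, under the minimum of 50 used for classes. Over all kept cells Il17a was 4.31, 275 and 60.4 CPM, and the γδ T-like class held 87.7%, 94.6% and 79.6% of those UMIs. Cells with an Il17a UMI were 30.95% (23.0 to 39.8%) of the class in the uninfected library, 51.8% (49.6 to 54.0%) on day 7 and 47.0% (41.4 to 52.7%) on day 14. At 1000 UMIs per cell these Il17a shares were 16.8%, 44.6% and 39.3%, leaving out 1, 70 and 10 cells. B-like cells gave 0 of 1467, 0.585% and 0.110% for Il17a, with an interval of up to 0.251% around 0 of 1467. Day 7 Il17a was 3.117 CPM in B-like but 219.0 CPM in alveolar type 1-like cells, so B-like cells may understate free RNA. Median UMIs per cell were 3618.5, 3152 and 2327 in the γδ T-like class and 2270, 2201 and 2014 in B-like cells.

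Il17f, Il22 and Ccr6 did not follow Il17a in ratios over uninfected. These ratios are against the mixed uninfected class, of which 99 of 126 cells joined innate lymphoid type 2-like clusters at the doubled resolution. How far such cells set the ratios was not tested. Il17f, the closest relative of Il17a, was −1.45 (−2.002 to −0.86) on day 7 and −2.96 (−4.39 to −1.76) on day 14 relative to uninfected. Among all Trdc-positive cells with Cd3 (42 uninfected cells) the day 7 Il17f value was positive with an interval that held 0. Il22, a cytokine that acts on epithelium, was −5.99 (−6.585 to −5.43) and −2.615 (−3.18 to −2.08), and Ccr6, a homing receptor of type 17 cells, −4.61 (−5.34 to −3.91) and −2.56 (−3.575 to −1.645). The IL-23 receptor gene Il23r was −0.76 (−1.09 to −0.42) and −1.61 (−2.15 to −1.075), and the IL-1 receptor gene Il1r1 −0.33 (−0.70 to 0.065) and 0.29 (−0.16 to 0.74). Ifng, the type 1 cytokine interferon γ, was higher on both days, at 1.96 (1.02 to 3.09) and 3.20 (2.235 to 4.36). Csf2, which encodes the growth factor GM-CSF, was 0.91 (0.22 to 1.70) and 1.71 (0.96 to 2.55), and was lower, not higher, among single Trdc-positive cells. The epidermal growth factor relative Areg was 2.68 (2.245 to 3.15) and 1.07 (0.58 to 1.595), the latter negative when likely doublets were kept. From day 7 to day 14, Il17a differed by −0.037 (−0.099 to 0.025), Il22 by 3.37 (2.66 to 4.10), Ifng by 1.245 (0.97 to 1.515) and Il23r by −0.84 (−1.30 to −0.42). Among all Trdc-positive cells with Cd3 the Ifng difference was negative, with an interval that held 0.

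Gene lists fixed beforehand are described by the median log2 ratio of their members minus the median of all genes of the class, with the percentile of the list's median among 10000 random lists of matched expression. A list is called higher or lower, or stands out, only in the outer 5% of those random lists, counting both ends. A member counts as higher or lower at a 2-fold difference by size, if its level is at least 5% of that in the class that has most of it. The all-gene median, day 7 and day 14 over uninfected, was −0.49 and −0.33 in mononuclear phagocytes, −0.34 and −0.34 in alveolar macrophage-like, −0.31 and −0.26 in interstitial macrophage-like, −0.15 and −0.051 in monocyte-like, and 0.35 and −0.074 in neutrophil-like cells. It was −0.13 and −0.0034 in γδ T-like, −0.093 and −0.11 in αβ T-like, −0.12 and −0.10 in NK-like, −0.21 and −0.17 in B-like and −0.14 and −0.12 in endothelial-like cells. On day 7 it was 0.037 in alveolar type 2-like and −0.21 in fibroblast-like cells.

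In γδ T-like cells the type 17 list was lower on day 7 and neither higher nor lower on day 14, but both calls depended on the processing. Its median was −0.39 (percentile 0.20) on day 7, with 4 of 18 measured members higher (Il17a, Areg, Cxcr6 and Furin) and 6 lower. On day 14 it was −0.16 (percentile 18.09), with 4 of 17 higher and 6 lower. With doublets kept the day 7 list no longer stood out (percentile 71.42), and with a minimum of 100 summed UMIs the day 14 list was higher (percentile 99.28). The type 1 lymphocyte list of cytotoxic and interferon γ-linked genes was at 1.77 (percentile 100) and 1.97 (percentile 100). Tbx21, its lead transcription factor, was 1.71 (0.90 to 2.67) and 1.71 (0.81 to 2.735). The activation and checkpoint list was at 0.73 (percentile 99.98) and 0.675 (percentile 99.97), where Pdcd1, the gene of the inhibitory receptor PD-1, was 1.98 (1.67 to 2.305) and 1.79 (1.45 to 2.14). The proliferation list was at 1.98 (percentile 100) and 1.003 (percentile 99.98), with Mki67, a marker of cycling cells, at 4.54 (2.68 to 7.59) and 3.36 (1.40 to 6.46).

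Outside the lists, the γδ T-like genes with the firmest differences on day 7 included Plac8 at 6.845 (5.49 to 8.72) and Ly6a at 3.32 (3.08 to 3.58), a surface marker raised by interferon. AA467197, of unsettled function in T cells, had no UMI in the uninfected class and was at least 60.65-fold higher on day 7, against a floor of 3 counts. Lower on day 7 were Pxdc1 at −4.165 (−4.35 to −3.98), the chemokine receptor gene Ccr4 at −5.75 (−6.81 to −4.795) and Ret at −4.86 (−5.61 to −4.145), a receptor kinase gene. On day 14 Plac8 and Ly6a were again higher, at 5.72 (4.35 to 7.61) and 3.51 (3.26 to 3.77), and Ramp3 and Klf4 were lower, at −4.655 (−5.22 to −4.14) and −3.03 (−3.50 to −2.59). All γδ T-like ratios over uninfected are against the mixed uninfected class. When likely doublets were kept, the proliferation list and Mki67 were lower, not higher, on both days. The type 1 list on day 7 (percentile 70.36) and the activation list on day 14 (percentile 71.56) then no longer stood out. With a minimum of 100 summed UMIs, the proliferation list no longer stood out on day 14.

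**Figure D2:**
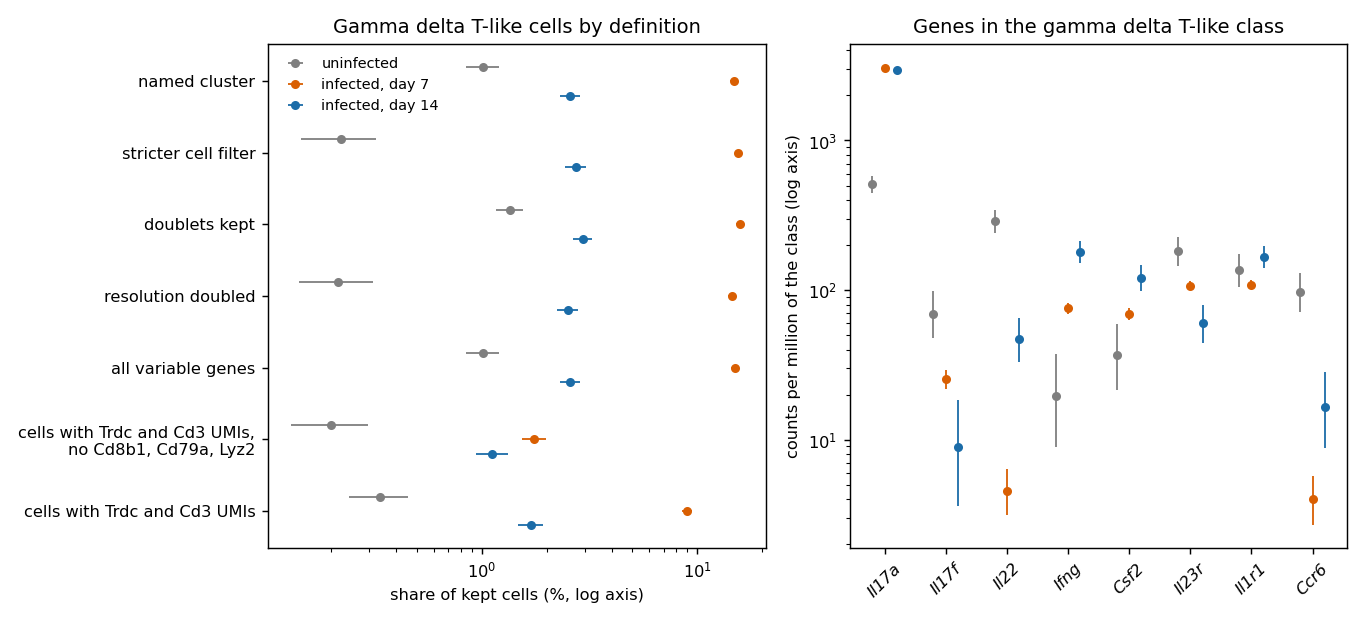
Left, share of kept cells (%, log axis) that each of 7 definitions counts as γδ T-like in the uninfected, day 7 and day 14 libraries, with exact 95% binomial intervals. Right, level of 8 cytokine and receptor genes in the named class (CPM, log axis), with exact 95% Poisson intervals; Il17a stands at 509.7, 3060 and 2982 CPM.

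The third comparison asks which cells carried the transcripts of IL-1β, IL-23 and related cytokines. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), which encodes the inflammasome-processed cytokine IL-1β, was 828 (816 to 840) CPM in uninfected mononuclear phagocytes, 3217 (3202 to 3233) on day 7 and 1781 (1762 to 1801) on day 14. Its log2 ratios over uninfected were 1.96 (1.94 to 1.98) and 1.11 (1.08 to 1.13), and the day 7 one was 2.45 under median-of-ratios scaling. Phagocytes held 54.2% of all Il1b UMIs in the uninfected library, 89.3% on day 7 and 48.6% on day 14, and the unnamed phagocytes alone held 69.45% on day 7. Neutrophil-like cells had the highest Il1b level of all classes, at 11510, 12110 and 19610 CPM, and held 13.030%, 2.88% and 47.5% of its UMIs. Day 7 Il1b was 1890 CPM in alveolar type 1-like cells, against 70.13 CPM in B-like cells.

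Within the phagocytes, Il1b in interstitial macrophage-like cells was 2.37 (2.285 to 2.45) on day 7 and 1.54 (1.46 to 1.63) on day 14. In monocyte-like cells Il1b was 0.81 (0.74 to 0.87) and 0.19 (0.13 to 0.24), and in alveolar macrophage-like cells 0.46 (0.41 to 0.50) and −1.04 (−1.195 to −0.89), so it was lower in the latter on day 14. Unnamed phagocytes carried Il1b at 4717 CPM on day 7 and 2945 on day 14. Conventional dendritic-like cells had Il1b ratios of 0.091 (0.053 to 0.13) and −0.69 (−0.76 to −0.62), of which the day 7 one was negative at a doubled resolution or with equal weight per cell. In neutrophil-like cells the Il1b ratio was 0.073 (0.016 to 0.13) on day 7, negative under median-of-ratios scaling or equal weight per cell, and 0.77 (0.72 to 0.815) on day 14.

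Il23a (ENSMUSG00000025383, chromosome 10, 128296139 to 128298752), the subunit specific to IL-23, was 9.95 (8.67 to 11.4) CPM in uninfected phagocytes, 14.9 (13.9 to 15.960) on day 7 and 5.39 (4.37 to 6.58) on day 14. Its highest level lay in neutrophil-like cells, at 26.65 (12.8 to 49.0), 419 (362 to 482) and 247 (223 to 273) CPM, with ratios of 3.97 (3.06 to 5.06) and 3.21 (2.32 to 4.28). Of all Il23a UMIs, unnamed phagocytes held 65.6% on day 7 and neutrophil-like cells 74.0% on day 14. Alveolar macrophage-like cells had Il23a at 15.1, 1.65 and 1.425 CPM. Cells with an Il23a UMI were 4.30%, 19.85% and 11.4% of neutrophil-like cells, 2.96%, 16.5% and 11.0% at 1000 UMIs (17, 38 and 194 cells left out). In B-like cells Il23a was seen in 0 of 1467, 0.0976% and 0.165%. Median UMIs of neutrophil-like cells were 1812, 1781.5 and 1375.

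Il12a, the subunit specific to IL-12, stood at 0.0922 CPM in uninfected phagocytes (2 UMIs), 47.6 on day 7 and 13.1 on day 14, with log2 ratios of 9.01 (7.16 to 12.06) and 7.15 (5.28 to 10.20). Il12b, the subunit that IL-12 and IL-23 share, was 2.705 (2.255 to 3.19) and 1.59 (1.06 to 2.15) in phagocytes. Its level was highest in conventional dendritic-like cells, at 719, 708 and 512 CPM. Within the phagocytes, Il12b stood at 13.66, 48.24 and 9.698 CPM in interstitial macrophage-like cells. Unnamed phagocytes had it at 2.415 CPM on day 7 and 3.42 on day 14. Neutrophil-like cells, which had the highest Il23a level, held 0, 2 and 0 Il12b UMIs. Cluster 17 held the most uninfected conventional dendritic-like cells (334) and cluster 16, whose leading genes include Il12b, the most on day 7 (474) and day 14 (107), against 145 uninfected cells. Il1a, the other IL-1 gene, was 1.14 (1.10 to 1.19) on day 7 and −0.525 (−0.59 to −0.46) on day 14 in phagocytes. The classes differed: Il1a stood at 378.5, 258.9 and 71.23 CPM in alveolar macrophage-like cells. It was 39.55, 179.3 and 95.95 CPM in interstitial macrophage-like and 8.207, 24.68 and 14.43 CPM in monocyte-like cells, higher than uninfected on both days. Il18 over all phagocytes was lower, at −2.30 (−2.37 to −2.24) and −2.36 (−2.46 to −2.26), but the classes differed: it was −1.125 (−1.19 to −1.06) and −0.63 (−0.78 to −0.48) in alveolar macrophage-like, −0.66 (−1.04 to −0.27) and 0.42 (0.059 to 0.80) in interstitial macrophage-like and 1.10 (0.49 to 1.67) and 0.71 (0.25 to 1.16) in monocyte-like cells. Tnf over all phagocytes was lower too, at −1.11 (−1.14 to −1.07) and −1.80 (−1.86 to −1.745). Tnf in neutrophil-like cells was 3.835 (3.44 to 4.26) and 2.52 (2.13 to 2.94). Il6 in phagocytes was 0.022 (−0.065 to 0.11) and −1.83 (−2.005 to −1.66), but the classes differed. It stood at 98.65, 42.21 and 19.23 CPM in alveolar macrophage-like and 27.83, 18.19 and 19.71 CPM in monocyte-like cells. In interstitial macrophage-like cells Il6 was 3.595, 34.2 and 12.89 CPM, higher than uninfected on both days. The whole IL-1 and IL-23 pathway list was at 1.035 (percentile 99.99) and 0.69 (percentile 99.87) in phagocytes, and at 1.845 (percentile 99.99) and 1.52 (percentile 99.94) in neutrophil-like cells.

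**Figure D3:**
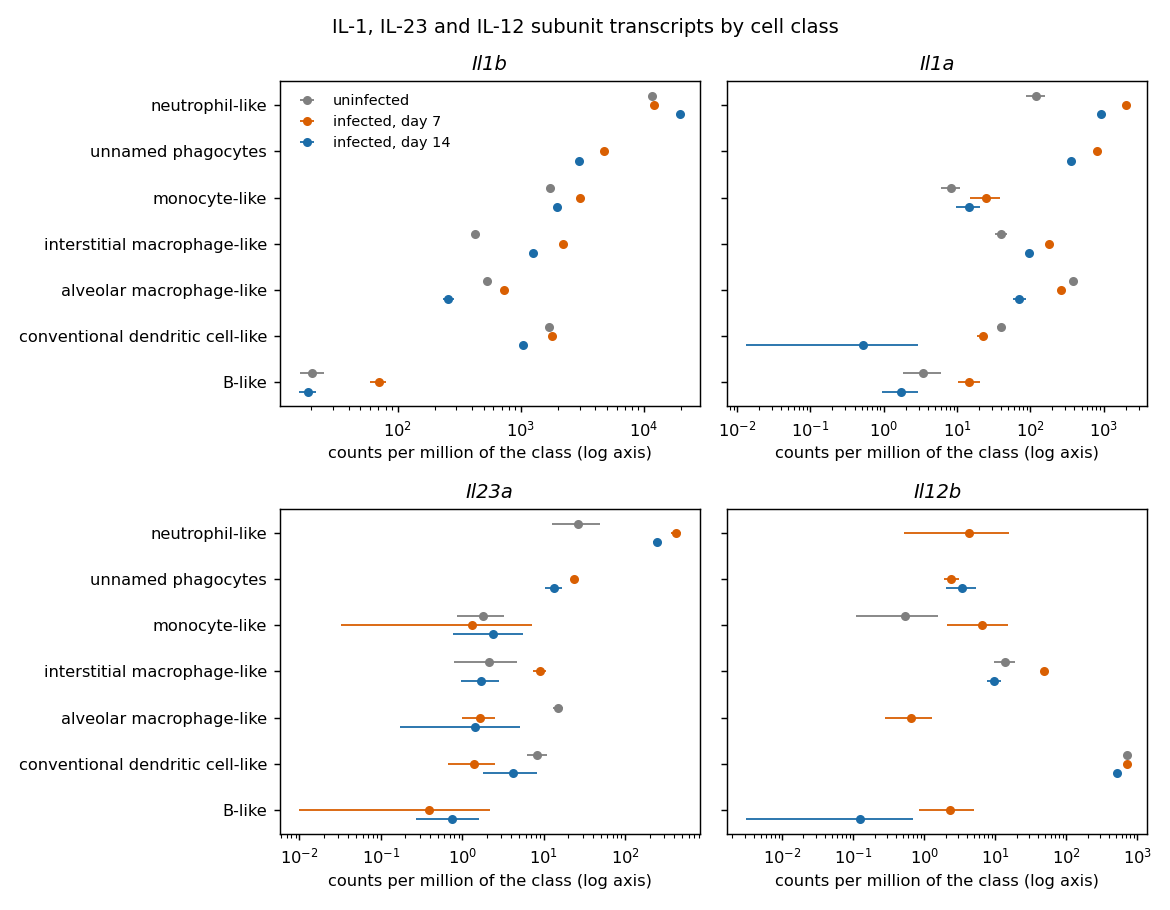
Level of Il1b, Il1a, Il23a and Il12b (CPM, log axis) in 7 cell classes of the uninfected, day 7 and day 14 libraries, with exact 95% Poisson intervals. Classes without a UMI have no point, and B-like cells are shown as a measure of free RNA, which may be higher in other classes. Il1b and Il23a are highest in neutrophil-like cells, at 19610 and 247 CPM on day 14.

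The fourth comparison asks how the phagocytes differed in transcription. In mononuclear phagocytes as a whole, antimicrobial and interferon γ-response genes were higher in both infected libraries and genes of the alveolar macrophage identity were lower. Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), which makes nitric oxide against intracellular bacteria, had 2 UMIs in uninfected phagocytes, 991 CPM on day 7 and 462 on day 14, with log2 ratios of 13.39 (11.54 to 16.44) and 12.29 (10.44 to 15.34). Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute phase protein gene, was 2.72, 6030 and 5211 CPM. Acod1, whose product makes itaconate, was 4.99 (4.78 to 5.196) and 5.30 (5.09 to 5.51). The antimicrobial list was at 1.54 (percentile 100) on day 7, with 10 of 24 members higher and 3 lower, and at 1.11 (percentile 99.99) on day 14.

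Of the 27 measured interferon γ-response genes, 25 were higher in phagocytes on day 7 and 27 on day 14, with medians of 3.01 (percentile 100) and 3.30 (percentile 100). The T cell-attracting chemokine genes Cxcl9 and Cxcl10 were 3.78 (3.70 to 3.86) and 2.52 (2.46 to 2.58) on day 7. Antigen presentation by MHC class II was also higher, at 1.96 (percentile 100) and 2.24 (percentile 100), with H2-Ab1 at 2.23 (2.21 to 2.25) and 2.375 (2.36 to 2.39). The glycolysis and hypoxia list was at 2.09 (percentile 100) and 1.685 (percentile 100), and Slc2a1, the main glucose transporter gene, at 2.49 (2.37 to 2.605) and 2.355 (2.23 to 2.48). Oxidative phosphorylation genes had no member past 2-fold, with medians of 0.73 (percentile 97.43) and 0.37 (percentile 90), the day 7 list being called higher with doublets kept or equal weight per cell. The NF-κB and inflammatory list was at 0.72 (percentile 98.75) and 0.53 (percentile 99.3), where Ptgs2, the inducible prostaglandin synthase gene, was 3.69 (3.615 to 3.77) and 3.115 (3.03 to 3.20). With equal weight per cell that list no longer stood out on day 14.

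The alveolar macrophage identity list was at −1.31 (percentile 0) and −2.16 (percentile 0) in all phagocytes, with Siglecf, a surface lectin gene, at −2.52 (−2.63 to −2.41) and −3.16 (−3.38 to −2.95). Lipid handling genes split: Fabp4 was −3.15 (−3.22 to −3.07) and Fabp5 1.76 (1.73 to 1.78) on day 7, both fatty acid carrier genes, and the list's medians were 0.39 (percentile 74.5) and −0.12 (percentile 9.265), the latter called lower with equal weight per cell. The regulatory list split likewise, with Arg1 (arginase) at 5.19 (4.38 to 6.145) and Retnla, a marker of IL-4-exposed macrophages, at −4.14 (−4.24 to −4.05) on day 7, and medians of 0.89 (percentile 99.71) and 0.52 (percentile 98.84). On day 14 the regulatory list no longer stood out with doublets kept (percentile 67.86), with a minimum of 100 summed UMIs (percentile 89.48), under the stricter cell filter or with equal weight per cell. Neutrophil chemoattractants were at 0.22 (percentile 71.29) and −0.48 (percentile 1.83), higher on day 7 and no longer lower on day 14 with doublets kept, nor lower on day 14 under the stricter filter. Monocyte and lymphocyte chemoattractants were at −0.067 (percentile 12.47) and −0.11 (percentile 20.84), with Ccl5, which draws T cells, at 6.045 (5.98 to 6.11) on day 7. That list was lower on day 7 with all variable genes or a minimum of 100 summed UMIs, and on day 14 with doublets kept. Values over all phagocytes mix the classes, whose shares differed between the libraries.

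Within alveolar macrophage-like cells, Saa3 was 13.22 (10.74 to 18.52) on day 7 from 1 uninfected UMI, and Nos2, with none there, was at least 1912-fold higher on day 7 and 589.6-fold on day 14. Their interferon γ-response list was at 3.41 (percentile 100) and 3.05 (percentile 100), and their MHC class II list at 2.755 (percentile 100) and 3.31 (percentile 100), with H2-Ab1 at 3.795 (3.74 to 3.85) and 3.99 (3.92 to 4.05). Identity genes, which took part in clustering and naming, were lower even inside the class, at −0.50 (percentile 0) and −0.16 (percentile 2.13). The day 14 call ended at the doubled resolution, with all variable genes or with equal weight per cell. Fabp1, a fatty acid binding protein gene, was −4.41 (−4.55 to −4.27) and −3.275 (−3.56 to −3.00). The matrix protease genes Mmp2 and Mmp14 were 8.48 (7.33 to 9.94) and 7.06 (6.25 to 7.99) on day 14. Dissociation stress genes, which respond to tissue digestion, were lower, at −0.90 (percentile 0) and −1.64 (percentile 0), with Egr1 at −5.03 (−5.196 to −4.86) and −4.42 (−4.84 to −4.04). Most uninfected cells of the class lay in cluster 5 (2073 cells) and most day 7 and day 14 cells in cluster 23 (1066 and 193 cells). Cluster 42, with 1 marker among its leading genes, held 0 uninfected, 334 day 7 and 20 day 14 cells. Its leading genes include Ubd and H2-M2. How far it set the ratios of the class was not tested.

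Interstitial macrophage-like cells had Saa3 at 13.54 (11.06 to 18.84) and 13.82 (11.34 to 19.12) over 1 uninfected UMI, and Nos2 at 9.03 (6.55 to 14.34) and 9.33 (6.85 to 14.63), also over 1 UMI. Gpnmb, a gene of lipid-laden macrophages, was 7.17 (6.29 to 8.23) and 7.81 (6.93 to 8.87), and the lipid handling list was at 1.095 (percentile 100) and 1.055 (percentile 100). With doublets kept, the lipid handling list no longer stood out on either day, with a day 14 percentile of 47.95. Glycolysis and hypoxia genes were higher, at 1.89 (percentile 100) and 2.35 (percentile 100), with Slc2a1 at 2.51 (2.07 to 2.98) and 2.92 (2.48 to 3.39). Lower on day 7 were Retnla at −5.57 (−5.69 to −5.46) and the eosinophil attractant gene Ccl24 at −7.20 (−8.165 to −6.38). The interferon γ-response list was at 2.22 (percentile 100) and 2.62 (percentile 100), and the dissociation stress list at −0.83 (percentile 0) and −1.26 (percentile 0). Cluster 19 held the most uninfected cells of the class (412), cluster 28 the most on day 7 (679) and cluster 38 the most on day 14 (475).

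Monocyte-like cells had Cxcl9 at 5.24 (4.82 to 5.67) and 3.61 (3.20 to 4.05) and Cxcl10 at 6.26 (6.04 to 6.48) and 4.77 (4.55 to 4.99). Of 26 interferon γ-response genes, 25 were higher on day 7 and 26 on day 14, with medians of 3.51 (percentile 100) and 2.86 (percentile 100). The GTPase genes Iigp1 and Tgtp1, which act on vacuoles of intracellular microbes, were 6.31 (5.69 to 7.00) and 7.22 (5.28 to 10.32) on day 7. Mpo and Elane, granule genes of young myeloid cells, had no UMI on day 7 and were at least 14.1-fold and 11.95-fold lower. Clusters 2 and 6 made up the class, with 644 and 578 uninfected cells, 87 and 106 on day 7 and 473 and 167 on day 14.

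The fifth comparison asks how neutrophil-like cells differed. Interferon γ-response genes were higher in both infected libraries, and several antimicrobial genes of granules, such as Ngp, Camp and Ltf, were lower. All 24 measured interferon γ-response genes were higher on day 7, with a median of 4.14 (percentile 100), and 24 of 25 on day 14, at 4.18 (percentile 100). The guanylate-binding protein gene Gbp5 had no uninfected UMI and was at least 70.8-fold and 77.5-fold higher. Cxcl9 was 7.92 (5.43 to 13.23) and 7.99 (5.51 to 13.29), Cxcl10 5.67 (4.94 to 6.51) and 6.83 (6.104 to 7.665), and Ccl3, an inflammatory chemokine gene, 5.48 (5.14 to 5.84) and 3.78 (3.44 to 4.14). The list of monocyte and lymphocyte chemoattractants was at 4.46 (percentile 100) and 1.81 (percentile 99.89). Genes that macrophage-like cells also carry were high in the day 7 class as well: Saa3 was 8.83 (6.35 to 14.14) over uninfected. From day 7 to day 14, Ccl2 differed by −5.10 (−5.80 to −4.46), Nos2 by −4.66 (−5.43 to −3.96), Gpnmb by −4.09 (−4.54 to −3.67) and Saa3 by −3.48 (−3.735 to −3.23). Il1rn, which encodes the natural blocker of IL-1, was 2.55 (2.39 to 2.72) and 1.43 (1.27 to 1.59).

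Ngp, a granule protein gene of young neutrophils, was −11.96 (−17.26 to −9.48) on day 7, when 1 UMI was left, and −2.31 (−2.38 to −2.235) on day 14. Camp, the cathelicidin gene, was −6.098 (−6.55 to −5.68), and Ltf, the lactoferrin gene, −5.09 (−5.70 to −4.53) on day 7. The antimicrobial list was at −0.79 (percentile 10.4) and −0.52 (percentile 0.27), with 9 and 6 members lower, and the day 14 call ended under the stricter cell filter or with equal weight per cell. Most uninfected (184) and day 14 (567) cells of the class lay in cluster 26 and most day 7 cells (259) in cluster 41, which held 2 uninfected cells.

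The sixth comparison asks how the other lymphocytes differed. αβ T-like cells had Ifng at 3.77 (3.66 to 3.89) on day 7 and 3.55 (3.44 to 3.66) on day 14, and held 52.6%, 87.3% and 91.0% of all Ifng UMIs in the uninfected, day 7 and day 14 libraries. Il17a in them was 2.07, 101 and 29.6 CPM, and Il17f 0.153, 25.2 and 0.646. Il21, a helper T cell cytokine gene, was 7.90 (6.03 to 10.95) and 7.57 (5.71 to 10.63). The type 17 list was at 3.10 (percentile 100) and 1.745 (percentile 100), with 14 of 18 members higher on day 7, and the activation list at 0.93 (percentile 100) and 0.57 (percentile 100). Its members Tnfrsf4 (OX40) and Il2ra (the IL-2 receptor α chain) were 3.05 (2.96 to 3.135) and 2.71 (2.57 to 2.86) on day 7.

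The αβ T-like type 1 list split. Its medians were −0.26 (percentile 0.030) and 0.12 (percentile 91.95). With equal weight per cell the day 7 list was not called lower and the day 14 list was called higher. Its members differed, with Ifng higher, and Ccl5 at −2.765 (−2.80 to −2.73) and Eomes, a regulator of cytotoxic cells, at −3.03 (−3.54 to −2.56) on day 7. The quiescence gene Klf2 was −2.49 (−2.60 to −2.38) and S1pr5, a receptor for leaving tissue, −4.70 (−6.16 to −3.56). Tnf in αβ T-like cells was 2.18 (1.95 to 2.43) and 3.18 (2.96 to 3.40). The interferon γ-response list was at 1.57 (percentile 100) and 2.14 (percentile 100). Cluster 10, whose leading genes include Cd8a and Gzmk, held the most uninfected αβ T-like cells (512), against 148 on day 7 and 675 on day 14. Cluster 13, whose leading genes include Cd4, Tnfrsf4 and Ifng, held the most on day 7 (909) and day 14 (1539), against 349 uninfected. Ratios in αβ T-like cells thus mix clusters that took different parts of the class in each library. How far that set the ratios was not tested.

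NK-like cells had the type 1 list at 0.38 (percentile 99.94) and 0.44 (percentile 100), but it no longer stood out on day 7 under the stricter cell filter or with all variable genes, nor on day 14 with a minimum of 100 summed UMIs. Ifng there was at 0.98 (0.73 to 1.23) and 1.175 (0.99 to 1.36) and the granzyme gene Gzmk at 0.022 (−1.37 to 1.18) and 1.35 (0.67 to 2.01). Their proliferation list was at 1.22 (percentile 100) and 0.43 (percentile 100), of which the day 14 one no longer stood out when doublets were kept (percentile 59.9), and their interferon γ-response list at 0.88 (percentile 100) and 0.74 (percentile 100). The heat shock genes Hspa1a and Hspa1b were 3.18 (2.68 to 3.69) and 3.61 (3.22 to 4.01) on day 7. Both belong to the dissociation stress list, which is described here for alveolar and interstitial macrophage-like cells only. The difference was not confined to NK-like cells: day 7 Hspa1a was 7.11 (5.249 to 10.16) in plasmacytoid dendritic-like cells. From day 7 to day 14 Hspa1a differed by −3.225 in NK-like, −3.551 in B-like and −2.873 in γδ T-like cells. Cd3g, a T cell gene, was 2.71 (2.17 to 3.25) in the 188 day 7 cells of this class.

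B-like cells had 19 of 27 interferon γ-response genes higher on day 7 and 21 of 26 on day 14, with medians of 2.99 (percentile 100) and 2.57 (percentile 100). Tgtp1 was 6.12 (4.74 to 8.01) and 6.05 (4.69 to 7.935), and Ifit3, an antiviral gene, 3.60 (1.885 to 5.97) and 6.30 (4.75 to 8.585). Hemoglobin RNA, which comes from red cells, was lower in B-like cells of both infected libraries, at −8.23 (percentile 0) and −8.65 (percentile 0), with Hbb-bs at −10.93 (−11.88 to −10.13) and −11.85 (−12.56 to −11.22). The red cell gene Alas2 had 186 uninfected UMIs and none on either day, at least 42.7-fold lower on day 7 and 134-fold on day 14. Cluster 14 held the most uninfected B-like cells (900) and cluster 15 the most on day 7 (515) and day 14 (2268).

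The seventh comparison asks how structural cells differed. Endothelial-like cells had more proliferation transcripts in both infected libraries, at 3.42 (percentile 100) and 2.10 (percentile 100), with Mki67 at 4.39 (3.665 to 5.16) and 2.71 (1.93 to 3.53). Vascular activation genes were at 0.74 (percentile 100) and 0.52 (percentile 99.95). The vascular list of day 7 no longer stood out under the stricter cell filter (percentile 77.08) or with doublets kept. The adhesion genes Selp and Vcam1, which slow leukocytes in blood vessels, were 3.765 (3.09 to 4.47) and 2.06 (1.58 to 2.54) on day 7, and Cxcl9 was 6.50 (5.805 to 7.28). Lyz2 and Il1b, which phagocytes carry at high levels, were also highest in the day 7 endothelial-like class, at 205, 1172 and 146 CPM for Lyz2 and 8.77, 101 and 5.97 CPM for Il1b. The interferon γ-response list was at 2.42 (percentile 100) and 2.325 (percentile 100).

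Alveolar type 2-like cells, which make surfactant, were compared on day 7 alone, since the day 14 library held 47 of them. Their interferon γ-response list was at 4.603 (percentile 100) and their neutrophil chemoattractants at 2.71 (percentile 100). Cxcl5, a neutrophil attractant gene, and Saa3 had no uninfected UMI there and were at least 70.55-fold and 152-fold higher, and Lcn2, which binds bacterial siderophores, was 4.75 (4.665 to 4.84). The surfactant list was at −0.34 (percentile 2.765), with Sftpc at −1.13 (−1.14 to −1.12), and was called lower with doublets kept, at the doubled resolution, with all variable genes or with equal weight per cell. Fibroblast-like cells, with 45 on day 14, were likewise compared on day 7. Their interferon γ-response list was at 3.37 (percentile 100), their chemoattractants at 3.01 (percentile 100) and their extracellular matrix list at 0.82 (percentile 100). Saa3 was 8.75 (8.27 to 9.29), Cxcl13, which draws B cells, 7.40 (6.64 to 8.29), Ccl2, which draws monocytes, 3.04 (2.91 to 3.17), and the matrix genes Tnc and Postn 2.23 (1.33 to 3.11) and 1.24 (0.92 to 1.56). Cluster 18, whose leading genes include Col1a1 and Col3a1, held 496 uninfected and 107 day 7 cells of the class, and cluster 31 held 300 and 28.

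The last comparison asks how the interferon lists of day 14 stood against day 7. Type I interferon-response genes, the antiviral program of interferons α and β, were higher on day 14 than on day 7 in mononuclear phagocytes as a whole and in each single class listed here, while interferon γ-response genes lay closer together. The type I list, day 14 over day 7, was at 1.06 (percentile 100) in mononuclear phagocytes, 0.83 (percentile 100) in alveolar macrophage-like, 0.99 (percentile 100) in interstitial macrophage-like, 0.59 (percentile 100) in monocyte-like and 1.91 (percentile 100) in neutrophil-like cells. It was at 1.27 (percentile 100) in γδ T-like, 1.71 (percentile 100) in αβ T-like, 0.93 (percentile 100) in NK-like, 1.24 (percentile 100) in B-like and 0.59 (percentile 100) in endothelial-like cells. Over uninfected, the type I list was already higher on day 7, for instance 2.02 (percentile 100) in phagocytes, 1.345 (percentile 99.99) in neutrophil-like, 0.85 (percentile 100) in αβ T-like and 1.14 (percentile 100) in γδ T-like cells. Ifit3 in mononuclear phagocytes was 1.52 (1.31 to 1.75) on day 7 and 3.91 (3.70 to 4.13) on day 14.

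The interferon γ-response list, day 14 over day 7, was at 0.40 (percentile 100) in mononuclear phagocytes, −0.13 (percentile 2.885) in alveolar macrophage-like, 0.43 (percentile 100) in interstitial macrophage-like, −0.33 (percentile 0.76) in monocyte-like and 0.42 (percentile 79.73) in neutrophil-like cells. It was at 0.15 (percentile 98.61) in γδ T-like, 0.14 (percentile 98.19) in αβ T-like, 0.072 (percentile 78.32) in NK-like, −0.18 (percentile 0.37) in B-like and −0.023 (percentile 25.15) in endothelial-like cells. Its γδ T-like medians over uninfected were 1.20 (percentile 100) and 1.47 (percentile 100). Nos2, a member of this list, was lower on day 14 than on day 7 in several classes, for instance 462 against 991 CPM in mononuclear phagocytes. With equal weight per cell, the γδ T-like and B-like lists no longer stood out, and the alveolar macrophage-like and endothelial-like ones were lower on day 14. The γδ T-like list also fell inside the limits under the stricter cell filter and at the doubled resolution. Because the run code differs with day 14, this comparison also sets 1 run code against another.

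**Figure D4:**
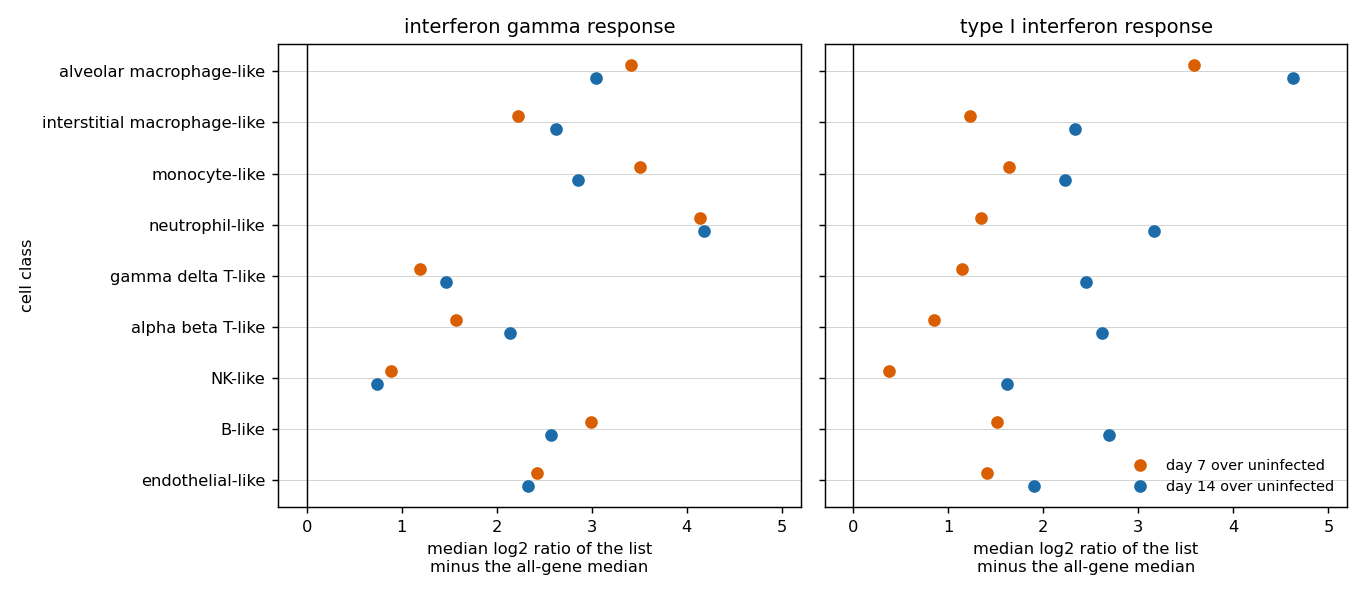
Median log2 ratio minus the all-gene median (horizontal axis) of the interferon γ-response list (left) and the type I interferon-response list (right) in 9 cell classes; each dot is 1 list in 1 class, day 7 or day 14 over uninfected. Type I medians lie higher on day 14 in each class shown, for instance 3.17 against 1.345 in neutrophil-like cells.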

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

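Some results went opposite ways on the 2 days: the log2 ratio over uninfected was above 0 in one infected library and below 0 in the other, with both 95% intervals excluding 0. That is what singled them out, and the difference between the days was not tested. No explanation was tested for them.

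αβ T-like cells had a share ratio of −0.51 on day 7 and 1.05 on day 14, and B-like cells −0.69 and 1.34, so both lymphocyte classes took a smaller part of the day 7 suspension and a larger part of the day 14 one. Mononuclear phagocytes went the other way, at 0.61 and −0.72. Plasmacytoid dendritic-like cells, the main makers of type I interferon, were at 0.96 and −0.52, the latter no longer detectable with doublets kept, and conventional dendritic-like cells at 0.30 and −1.24, the former −0.051 at the doubled resolution, with an interval that held 0, and no longer detectable among leukocytes alone. Shares of 1 suspension are tied to each other, so a larger share of one class lowers the others.

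Among cytokines, Il1a in mononuclear phagocytes was at 1.14 on day 7 and −0.525 on day 14, and Il23a there at 0.58 and −0.88. These values mix classes whose shares differed between the libraries. Alveolar macrophage-like cells held 88.04% of uninfected Il1a UMIs and 70.18% of uninfected Il23a UMIs, and were 18.04% of uninfected but 1.81% of day 14 cells. Day 14 Il1a was higher than uninfected in interstitial macrophage-like and monocyte-like cells. Il1b in alveolar macrophage-like cells was at 0.46 and −1.04, and Il1b in conventional dendritic-like cells at 0.091 and −0.69. The dendritic Il1b values no longer went opposite ways at the doubled resolution or with equal weight per cell, where the day 7 one was −1.002 and −0.069. Il18 in interstitial macrophage-like cells was at −0.66 and 0.42. The day 7 interval held 0 under median-of-ratios scaling or equal weight per cell, and the day 14 one with doublets kept.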

How the results depend on the processing

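All values here are log2 ratios, of shares or of levels, and list medians are given without the all-gene median taken off. Counting each alternative of each reported result once, 282 of 285 share ratios, 2839 of 2881 gene ratios and 1084 of 1104 list medians kept their direction. The γδ T share was higher in both infected libraries under each alternative run, between 3.13 and 6.13 on day 7. As a plain ratio per B-like cell, γδ T-like cells were at 0.0859 uninfected, 2.03 on day 7 and 0.0866 on day 14. Il17a in γδ T-like cells and Il1b in mononuclear phagocytes also stayed higher on both days. Leukocytes only, shallow clusters left out and Trdc-positive cells with no marker exclusion were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Where a value moved or turned, the cause was not tested. Of the list medians said to turn, those of proliferation in γδ T-like cells became called lower, and the others no longer lay past either percentile limit. The 95% interval held 0 for the turned dendritic share, Il17f and Ifng, for Csf2 from day 7 to day 14, and for day 7 Csf2 with no marker exclusion.

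Under the stricter cell filter, the γδ T share was 6.13 (day 7) and 3.62 (day 14) over uninfected. Day 7 endothelial-like cells had Ccl21a at 1.75, Mmrn1 at 1.11 and vascular activation at −0.016, each turned round.

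With doublets kept, the γδ T share was 3.54 on day 7 and the mononuclear phagocyte share −0.61 on day 14. In γδ T-like cells, Il17a was 3.36 and 2.93 on the 2 days. Mki67 turned to −1.04 and −0.92, proliferation to −0.77 and −0.76, day 7 Ube2c to −1.23 and the day 7 type 1 list to −0.096. On day 14 Areg turned to −0.52 and T cell activation to −0.036. The day 7 type 17 list was −0.072. Turned as well were NK-like proliferation (day 14, −0.049), lipid handling in interstitial macrophage-like cells (day 14, −0.049), regulatory genes in phagocytes (day 14, −0.18), Ccl21a and Mmrn1 in endothelial-like cells (day 7, 2.24 and 1.27) and Il1a in conventional dendritic-like cells (day 7, 0.47). On day 14 Il1b and Il23a in phagocytes were 1.14 and −0.45.

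At the doubled resolution, the γδ T share was 6.07 and 3.54. Conventional dendritic-like cells turned on day 7 in share (−0.051) and Il1b (−1.002), on day 14 in Il12b (0.11), and from day 7 to day 14 in interferon γ response (−0.015). With all variable genes, the phagocyte share was 0.50 on day 7. Median-of-ratios scaling gave Il1b at 2.45 and 1.43 in phagocytes on the 2 days, Il23a at 1.07 there on day 7 and Il1b at −0.27 in day 7 neutrophil-like cells, the last turned. Equal cell weight gave day 7 Il17a at 2.85 in γδ T-like cells, Il1b at 1.89 and Il23a at 0.90 in phagocytes, and Il1b turned to −0.14 in neutrophil-like and −0.069 in conventional dendritic-like cells. With a minimum of 100 UMIs, the day 14 type 17 list was 0.49 in γδ T-like cells, and regulatory genes in phagocytes turned to −0.0033.

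Among Trdc-positive single cells, the γδ T share was 3.13 and 2.48 and Il17a 3.30 and 3.47 on the 2 days. Csf2 turned to −1.73 and −2.345, and to −0.62 from day 7 to day 14. With no marker exclusion, the share was 4.74 and 2.33, Il17a 3.30 and 3.11, and Csf2 turned to −0.66, −1.12 and −0.46. Il17f turned to 0.33 on day 7, and Ifng to −0.30 from day 7 to day 14. Among leukocytes only, the phagocyte share was 0.36 and −1.02, and with shallow clusters left out 0.50 and −0.83.

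Genes and lists of γδ T-like cells could not be compared with uninfected cells under the stricter filter or the doubled resolution, which left 26 and 27 uninfected cells, under the minimum of 50. The Trdc-positive single cells also lay under that minimum, with 25 uninfected cells, or 42 with no marker exclusion. Their gene ratios over uninfected were given all the same and are weak checks. Depth limits the γδ T-like genes: with 126 uninfected cells, simulated 2-fold differences had their direction recovered for 59.7% of genes on day 7 and 65.0% on day 14. The simulation held counting error only.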

Other observations

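Plasma-like cells, which secrete antibody, were 0.184% (0.117 to 0.276%) of uninfected cells, 0.0921% (0.0491 to 0.1575%) on day 7 and 1.29% (1.10 to 1.503%) on day 14, a day 14 share 7.00 (4.50 to 11.4) times the uninfected one, and smaller but above 1 under the stricter cell filter or with doublets kept. Plasmacytoid dendritic-like cells were 0.912%, 1.78% and 0.636%. In conventional dendritic-like cells the interferon γ-response list was at 2.503 (percentile 100) on day 7 and 2.49 (percentile 100) on day 14 over uninfected, and the type I list at 1.91 (percentile 100) and 3.29 (percentile 100). In plasmacytoid dendritic-like cells the interferon γ-response list was at 1.97 (percentile 100) and 1.37 (percentile 100), and the type I list at 0.48 (percentile 96.94) and 1.43 (percentile 100), the day 7 one called higher under the stricter cell filter or with doublets kept.

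Technical explanations were weighed for 3 patterns. The tests of the γδ T share and of the run code were chosen after the result was seen; both tests of free RNA from phagocytes were chosen before.

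γδ T-like cells made up a larger share of the day 7 library than of the uninfected one. The tables argue against a loss of structural cells as the cause, since the day 7 share was still 12.3 times the uninfected one among leukocytes alone. They also argue against free Trdc RNA, as far as B-like cells measure it, since 0.0976% of day 7 B-like cells had a Trdc UMI. The γδ T-like class was at 57.8%, but Trdc was among the markers that named the class, so that value was partly set in advance. Cells of other types inside the uninfected class bear on the size of the fold, which was 14.6 as reported, 67.04 at the doubled resolution, 26.7 for cells with Trdc and Cd3 UMIs and 8.75 where cells with Cd8b1, Cd79a or Lyz2 were also left out, so the size stays open. Growth or entry of γδ T cells during infection may explain the higher share, as a hypothesis that was not tested, and a difference between animals stays open because each group has 1 library.

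Interferon γ-response genes were higher on day 7 in αβ T-like, NK-like, B-like and endothelial-like cells, which are not phagocytes. If free RNA from phagocytes were the cause, the list's median gain, as a percent of its day 7 level in unnamed phagocytes, would lie at or under the highest percent that Saa3, Lyz2 and Il1b reach in those cells. It was 3.8 times that highest percent in NK-like, 21.25 times in αβ T-like, 21.46 times in B-like and 28.23 times in endothelial-like cells. These values argue against free RNA from unnamed phagocytes as the cause. Free RNA from other cells, including the other phagocytes, was not tested. A response of these cells to interferon γ during infection is a candidate explanation, found and weighed on the same libraries. Other technical differences between the libraries were not tested and stay open.

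Type I interferon-response genes were higher on day 14 than on day 7. The same test of free RNA from phagocytes gave a gain of at least 15.68 times the highest percent in each of the 4 classes, the lowest being NK-like cells. That argues against free RNA from unnamed phagocytes, and other cells were not tested as its source. A difference between sequencing runs, if the run code marks one, cannot be told apart from day 14, because 1 library carries the later run code and no day 7 or uninfected library shares it. A later wave of type I interferon during infection may also explain the pattern and was not tested.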
